A study of Mus musculus with 2 samples.

How the data were processed

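Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured in hindbrain tissue of mouse embryos at embryonic day 15.5. Per the labels, there were 2 biological replicates, each a pool of tissue from many embryos of both sexes, 78 embryos in replicate 1 and 62 in replicate 2. The labels name 1 group, so no treated, control or other-tissue sample could be compared. Input libraries were not analysed here.

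The authors deposited peak lists in narrowPeak form. Each replicate had its own list, and 2 further lists covered both replicates: peaks called on the replicates together (the pooled list), and a subset of these that the authors named replicated. The peak caller, its version, the aligner and the rule for the replicated list are not given in the sources used here. Coordinates are on mm10, and every peak lay within the length of its chromosome in the reference of the same assembly. Each peak carries a fold enrichment (a ratio), as the authors deposited it, and its significance as the -log10 of a p-value and of a q-value, also as deposited. These values belong to single peaks and were used only to describe, rank or filter peaks within a list. The files give neither read counts nor depth, so the depth behind each replicate is unknown, and the absence of a peak from a list sets no upper bound on the mark there.

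The comparisons used peaks on the 21 assembled chromosomes, except that the description of the whole lists and the comparison of the replicated list with the other lists also held the few peaks on unplaced sequences. Genes and transcription starts came from the GENCODE M21 annotation of the same assembly, which holds 21938 protein-coding genes on these chromosomes. A gene had a promoter peak when a peak touched the window of 1 kb either side of the start of any of its coding transcripts. Where several peaks did, the fold given for a gene is the highest among them and the width is that of the widest. The covered length around a gene was the number of base pairs under peaks within 25 kb either side of its 5' end, the outermost annotated start. Values are of the replicated list unless a replicate is named. A mean ± SD with n = 2 is of the values from the replicates' own lists.

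Peak sets were compared by overlap, and a peak counted as shared when the overlap was at least 50% of either peak. Chance overlap came from 100 circular shifts of a list within each chromosome, with a one-sided permutation test whose smallest possible p is 0.0099. Shifts ran over the full length of a chromosome, and unsequenced stretches were not left out. Peaks were assigned by their centre to a promoter window, an exon, an intron or the space between genes, in that order, and the shares were set against 100 shifts. For this assignment, promoter windows were those of all annotated transcripts, coding or not. The p of a share is one-sided, was taken on the side where it was smaller, and was not doubled. The 26 gene lists, of 11 to 25 members each, held regional patterning factors, cell type markers and reference genes. They were fixed before the data were examined, as were the tests of the report, the rule for named genes and all alternatives except those named at the end. Of all members, 1 (Ahsp, in the erythroid list) was not in the annotation. For each list, the share of members with a promoter peak was compared with all other protein-coding genes by Fisher's exact test, two-sided. The median covered length was compared with 100000 random gene lists of the same size by a two-sided permutation test, whose smallest p is 2e-05. Both sets of p-values were adjusted over the 26 lists by the Benjamini-Hochberg method, and 0.05 was the threshold. Binomial intervals are exact (Clopper-Pearson) at 95%. Contrasts between lists used Fisher's exact test and a permutation test with 100000 resamples, two-sided, whose smallest p is 1e-05. These tests treat genes as the units: they describe the peak lists of this tissue and do not measure spread between animals. Neighbouring genes share peaks and are not independent.

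The named genes were the 25 protein-coding genes under the widest replicated promoter peaks, and for each list up to 4 members with the most covered base pairs and up to 3 members, in alphabetical order, with no promoter peak in either replicate. All Hox genes, the gene nearest to each of the 10 peaks of highest fold over 5 kb from any annotated start, and the protein-coding genes in the 10 merged groups of peaks with the most covered base pairs were added. Merged groups joined peaks with gaps of at most 10 kb.

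The alternatives were other promoter windows (500 bp and 2 kb), other surrounding windows (10 kb and 50 kb; 2 kb for the Hox genes), other overlap rules (1 bp, or 50% of both peaks), stricter thresholds (-log10 q of at least 2 or 5), the 20000 peaks of highest fold, the pooled list, other merging gaps (5 kb and 20 kb), random lists matched on gene density, 1 member per 100 kb, and each replicate alone. The replicated peaks that overlap a peak of both replicates were added as an alternative after the data were seen, as were the other overlap rules for the comparison by fold rank. The overlap functions were tested on simulated intervals against bedtools, with 0 differences over 2300 items. The list tests were run on the real genes with shuffled values. Shuffling removes the sharing of peaks between neighbours, so the rates do not apply to lists of neighbouring genes such as Hox genes. With 95% of the members of planted lists given a promoter peak, 81.3% of 80 planted lists passed, and 1.54% of 260 shuffled lists did. With the covered length of members raised to over 4 times its value, 97.5% of 80 planted lists passed, and 0 of 260 shuffled lists did. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with bedtools 2.31.1, samtools 1.23.1 and matplotlib 3.10.9.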

Results

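H3K27ac was profiled by ChIP-seq in the hindbrain of embryonic day 15.5 mice, in 2 biological replicates made from pools of 78 and 62 embryos. The hindbrain holds the medulla, the pons and the growing cerebellum. The data are peak lists, and the number of reads behind them is not given. The list of replicate 1 held 93524 peaks and that of replicate 2 held 82431 peaks, a mean of 87978 ± 7844 (SD, n = 2). They covered 53.2 Mb and 47.4 Mb of the genome. The pooled list, called on the replicates together, held 108803 peaks over 68.4 Mb, and the replicated list held 56148 of these over 54.7 Mb. Peaks of the replicated list had a median width of 671 bp and a median fold enrichment of 3.76, the authors' value per peak. In the replicated list 78.0% of peaks had a -log10 q of at least 5, against 43.4% in the pooled list from which it was drawn. The share was 35.2% in replicate 1 and 38.2% in replicate 2. Those q-values come from calls on a single replicate and cannot be set directly against calls on both together.

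The first comparison was between the replicates. Of the peaks of replicate 1, 52.6% were shared with replicate 2, and of the peaks of replicate 2, 62.1% were shared with replicate 1. Shifted lists shared 2.62% and 2.97%, and no shift reached the observed share (one-sided permutation p = 0.0099 for each direction, the smallest that 100 shifts allow). Of 21938 protein-coding genes, 12276 had a promoter peak in both replicates, 504 in replicate 1 alone, 265 in replicate 2 alone and 8893 in neither. Sharing fell with the fold of the peak, but width fell with fold too, and their effects were not separated. The median width was 1602 bp in decile 1 and 228 bp in decile 10 of replicate 1. In replicate 2 it was 1544 bp and 231 bp. In decile 1, the peaks of highest fold, 100% were shared in both directions. In decile 3, 80.7% of replicate 1 peaks and 88.7% of replicate 2 peaks were shared. The lowest values were 24.5% in decile 8 of replicate 1 and 34.6% in decile 9 of replicate 2, and decile 10 had 27.6% and 42.2%. The replicated list held every pooled peak that overlapped a peak of both replicates by this rule, 46454 peaks, and 9694 further peaks (17.3% of the list) that lacked one or both replicates.

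**Figure D1:**
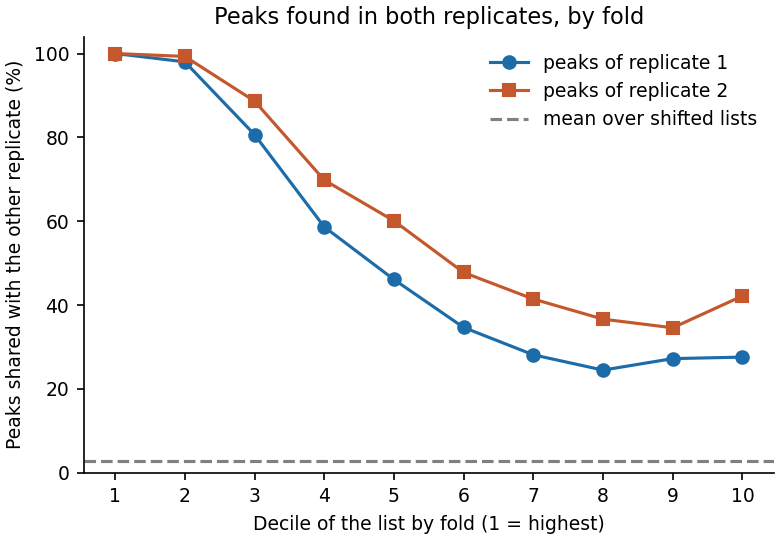
Share of each replicate's peaks (vertical axis, percent) that overlapped a peak of the other replicate by at least 50% of either peak, by decile of the authors' fold (horizontal axis, 1 is the highest). Circles are peaks of replicate 1, squares peaks of replicate 2, and the dashed line is the mean over shifted lists, taken over all deciles and both directions together.

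The second question was where in the genome the mark lay. Promoter windows of all annotated starts, coding or not, held 17686 of the replicated peaks, 31.5%, against 6.20% for shifted lists. Introns held 42.3% against 39.4%, exons 3.69% against 3.32%, and the space between genes 22.5% against 51.1% (one-sided permutation p = 0.0099 for each class, the smallest possible). Shifted peaks could fall on stretches where no peak can be called, so the small differences for introns and exons cannot be read as enrichment. With replicated peaks of -log10 q at least 5 the share in introns was 38.1%, below that of shifted lists (permutation p = 0.099), and the share in exons was 3.42%, above it (p = 0.168), so that introns changed direction and exons no longer passed. Promoter peaks were wider, with a median of 1073 bp against 573 bp in introns, and their median fold was 7.78 against 3.35. Over 5 kb from any annotated start lay 28993 peaks, 51.6%. A replicated promoter peak was present at 12429 of the protein-coding genes, 56.7%.

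Genes of neurons and of the granule cell lineage had promoter peaks more often than other genes, as housekeeping genes did. All 20 pan-neuronal genes had a promoter peak, among them Tubb3 (neuronal beta-tubulin), Rbfox3 (the splicing factor NeuN), Ina (alpha-internexin) and Celf4. So did 23 of the 25 genes of the cerebellar granule and rhombic lip lineage, 19 of the 22 neural progenitor genes, 14 of the 16 glutamatergic synapse and transporter genes and 13 of the 15 Sonic hedgehog pathway genes. Some genes stand in several lists, such as Ptch1 and Gli2 in the granule and the Sonic hedgehog lists, so these lists are not independent. In the other direction, the markers of several small neuron classes were mostly without promoter peaks, with 4 of 16 serotonergic and noradrenergic genes and 3 of 15 cranial motor neuron genes carrying one.

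Each of these shares was compared with that of all other protein-coding genes by Fisher's exact test, with Benjamini-Hochberg adjustment over the 26 lists. The share was 100% for pan-neuronal genes (95% interval from 83.2% to 100%, adjusted exact p = 9.87e-05) and 92.0% for the granule and rhombic lip list (74.0% to 99.0%, adjusted exact p = 0.000543). It was 86.4% for neural progenitors (65.1% to 97.1%, adjusted exact p = 0.0104), 87.5% for glutamatergic genes (61.7% to 98.4%, adjusted exact p = 0.0233) and 86.7% for the Sonic hedgehog pathway (59.5% to 98.3%, adjusted exact p = 0.0345). Housekeeping genes, a reference list, had 20 of 20 (adjusted exact p = 9.87e-05). The shares of the serotonergic and noradrenergic list, 25% (7.27% to 52.4%, adjusted exact p = 0.0345), and of the cranial motor list, 20.0% (4.33% to 48.1%, adjusted exact p = 0.0148), were lower than that of other genes. Neither of these 2 calls held in all 8 alternatives. The cranial motor list did not pass with replicate 2 peaks alone (33.3%, adjusted exact p = 0.0973) or with the pooled list (46.7%, 0.487), with a range of adjusted p from 0.0150 to 0.487. The serotonergic and noradrenergic list did not pass with replicate 1 peaks alone (37.5%, adjusted exact p = 0.157), with the pooled list (37.5%, 0.109) or with 2 kb windows (31.3%, 0.0644), with a range from 0.00162 to 0.157. Of the higher lists, neural progenitors did not pass with -log10 q of at least 5 (77.3%, adjusted exact p = 0.0791; range from 0.00482 to 0.0791) and the Sonic hedgehog list not with 2 kb windows (86.7%, 0.0571; range from 0.00106 to 0.0571).

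The length of marked sequence around the gene separated the lists further. Within 25 kb of their 5' ends, protein-coding genes had a median of 1588 bp under replicated peaks. The median was 7356 bp for the granule and rhombic lip list, 6046 bp for astrocyte genes, 5472 bp for the Purkinje and GABAergic lineage, 5454 bp for neural progenitors, 5332 bp for hindbrain and isthmus patterning factors and 4383 bp for pan-neuronal genes. Housekeeping genes had 3622 bp. Both front Hox lists were higher still, with 23757 bp for groups 1 to 4 and 26104 bp for groups 5 to 8. These 9 lists were higher than random lists (permutation test with 100000 random lists, adjusted permutation p from 0.000104 to 0.0191). None of the 26 was called lower, but 6 lists (Hox groups 9 to 13, cranial motor, telencephalic, erythroid, liver and epidermal) had a median of 0 bp, the lowest possible, and so could have no smaller p. At unadjusted permutation p, the Hox groups 9 to 13 (p = 0.0456) and the telencephalic list (p = 0.0196) lay below random lists and the glutamatergic list above (p = 0.0429), with adjusted p of 0.0987, 0.0511 and 0.0987. With 50 kb windows, the telencephalic and epidermal lists had lower medians than random lists (adjusted permutation p = 0.00641 and 0.0235), and Hox groups 9 to 13 a higher one (6099 bp, adjusted permutation p = 0.0478). Over the 9 alternatives the adjusted p ranged from 0.00641 to 0.301 for the telencephalic list, from 0.0235 to 0.310 for the epidermal list and from 0.0102 to 0.890 for Hox groups 9 to 13. The glutamatergic list was higher with 10 kb windows (adjusted permutation p = 0.00598) and with random lists matched on gene density (0.0283; range from 0.00598 to 0.572), and the Sonic hedgehog list with matched lists (0.0252; range from 0.0252 to 0.219).

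**Figure D2:**
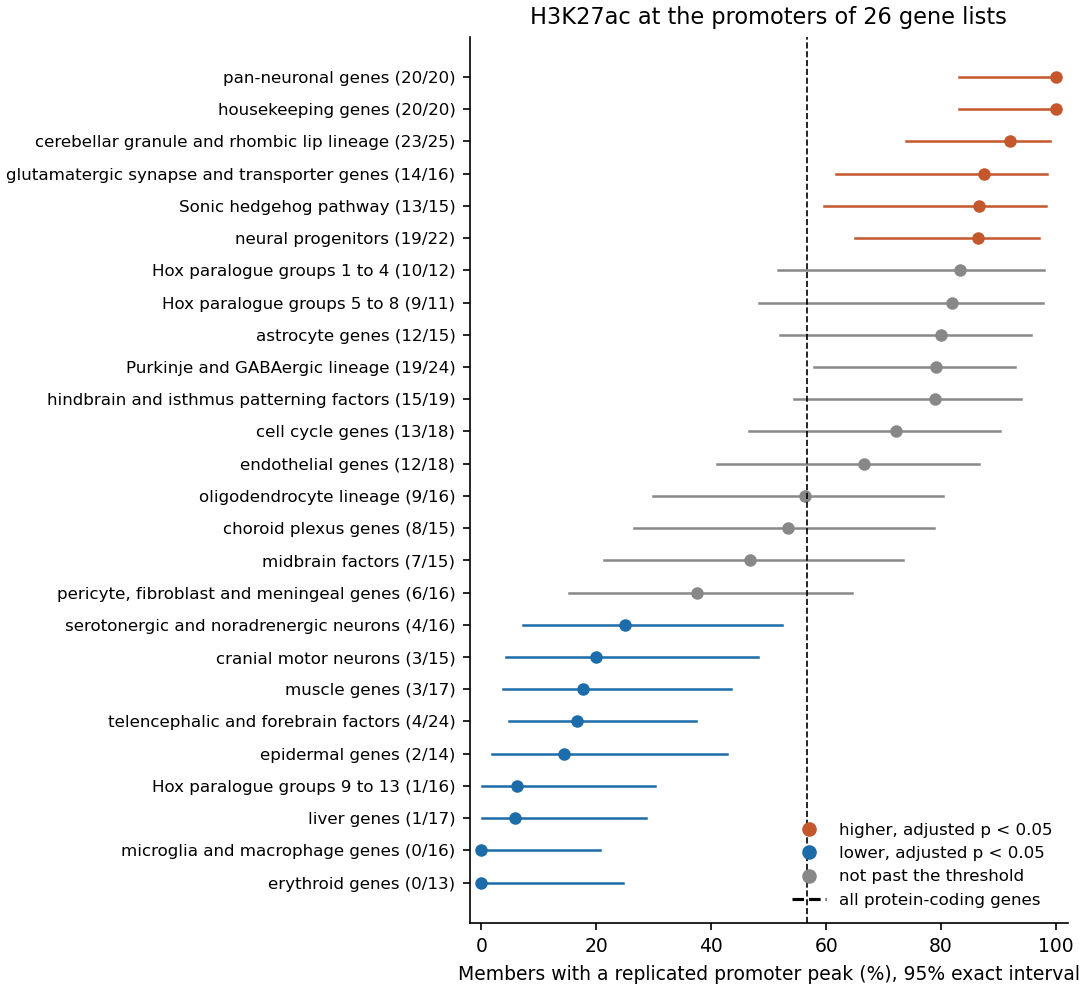
Share of the members of each of the 26 gene lists with a replicated promoter peak (horizontal axis, percent; bars are exact 95% binomial intervals), with counts beside the list names and a dashed line at the 56.7% of all protein-coding genes. The 6 lists in orange were higher and the 9 in blue lower (adjusted p under 0.05), and the 11 in grey did not pass.

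In the granule and rhombic lip list, the Zic genes, zinc finger factors of granule cell precursors and granule neurons, had the most marked sequence. Zic1 had 35620 bp within 25 kb (33705 ± 1748 bp, SD, n = 2), Zic4 34393 bp (32596 ± 1485 bp, n = 2), Zic2 30232 bp (27551 ± 1107 bp, n = 2) and Zic5 30134 bp (27608 ± 1238 bp, n = 2). Zic1 and Zic4 lie head to head on chromosome 9 and share much of this sequence, as Zic2 and Zic5 do on chromosome 14. The members without a replicated promoter peak were Eomes, a factor of unipolar brush cells, which had none in either replicate, and Atoh1, the factor that specifies the rhombic lip, which had one in replicate 1 alone. In the Purkinje and GABAergic lineage, 19 of 24 genes had a promoter peak (79.2%, 57.8% to 92.9%, adjusted exact p = 0.0602). With replicate 1 peaks alone the share was 87.5% and with replicate 2 peaks alone 83.3%, and both passed (adjusted exact p = 0.00730 and 0.0217; range over 8 alternatives from 0.00239 to 0.0614). Ebf3 had 28846 bp (27295 ± 938 bp, n = 2), Bcl11a 23982 bp, Lhx5 23030 bp and Lhx1 19386 bp (18675 ± 694 bp, n = 2). Lhx1 and Lhx5 are factors of early Purkinje cells. Ptf1a, the factor that specifies the GABAergic lineage of the cerebellum, and the Purkinje markers Calb1 and Pcp2 had no promoter peak in either replicate.

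Among progenitor genes, Sox2, a factor of neural stem cells, had 26606 bp (24331 ± 1805 bp, n = 2), Notch1 21799 bp, Id3 13393 bp and the RNA-binding protein gene Msi1 12897 bp. Dbx1 and Neurog1 had no promoter peak. In the Sonic hedgehog pathway, which drives the division of granule cell precursors, the receptor gene Ptch1 had 17251 bp (15917 ± 155 bp, n = 2), Boc 9668 bp, Gli2 7023 bp and Smo 4503 bp. Among glutamatergic genes, Dlg4 (PSD-95) had 18032 bp, and the vesicular transporter gene Slc17a6 (VGLUT2) had 13590 bp (12983 ± 105 bp, n = 2), Shank1 had 4859 bp and Grin2b 4728 bp, while the vesicular transporter genes Slc17a7 (VGLUT1) and Slc17a8 (VGLUT3) had no promoter peak. Of the cell cycle genes, 13 of 18 had a promoter peak (72.2%, adjusted exact p = 0.279), with Ccnd1 at 4956 bp and Mcm2 at 4616 bp. This list passed with the pooled list (88.9%, adjusted exact p = 0.0240) and with replicate 1 peaks alone (83.3%, 0.0456), with a range over 8 alternatives from 0.0240 to 0.291. Aurkb, with 10966 bp in its surroundings, had a promoter peak in replicate 2 alone.

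The small neuron classes differed within their lists. Lmx1b, a factor of serotonergic neurons with wider use in the hindbrain, had 17546 bp (15205 ± 688 bp, n = 2) and a promoter peak of fold 7.19. Gata3 had 5184 bp, with a promoter peak of fold 2.63. The serotonergic factor gene Fev (Pet1), the noradrenergic enzyme gene Dbh and Foxa1 had no promoter peak, and Th had 1386 bp without one. Among cranial motor genes, Nkx6-1 had 1869 bp, Ret 1320 bp and Tbx3 395 bp, each with a promoter peak. Chat, which encodes the enzyme of acetylcholine synthesis, Isl2 and Lhx3 had no promoter peak and 0 bp within 25 kb.

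Glial genes were in part marked. Of the astrocyte genes, 12 of 15 had a promoter peak (80.0%, 51.9% to 95.7%, adjusted exact p = 0.107), 14 of 15 in replicate 1 and 11 of 15 in replicate 2. The share of 93.3% in replicate 1 passed (adjusted exact p = 0.0130; range over 8 alternatives from 0.0130 to 0.336). Atp1a2 had 13845 bp, Sparcl1 13472 bp, the glutamate transporter gene Slc1a2 (GLT-1) 10014 bp (8741 ± 1422 bp, n = 2) and Aldh1l1 8472 bp, while Gjb6 had no promoter peak. Of the oligodendrocyte lineage, 9 of 16 genes had one, a share of 56.3% beside 56.7% of other genes (adjusted exact p = 1). Sox8 had 12777 bp, and Cspg4, Gpr17 and Mag had no promoter peak in either replicate.

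The Hox genes were compared by position in their clusters, since groups 1 to 4 are expressed in the hindbrain and groups 9 to 13 in the trunk. Groups 1 to 4 had a promoter peak at 10 of 12 genes and groups 9 to 13 at 1 of 16 (Fisher's exact p = 4.97e-05, two-sided). Within 5 kb of the 5' end, groups 1 to 4 had a mean of 5265 bp under peaks and groups 9 to 13 a mean of 23.6 bp (permutation p = 1e-05, two-sided, the smallest that 100000 resamples allow). Hoxb1 and Hoxd1 were the genes of groups 1 to 4 without a promoter peak, and neither replicate had one there. The gene of groups 9 to 13 with one was Hoxb9, by a peak of 378 bp with a fold of 3.11. The other 15, Hoxa9, Hoxa10, Hoxa11, Hoxa13, Hoxb13, Hoxc9 to Hoxc13 and Hoxd9 to Hoxd13, had none in either replicate. Of groups 5 to 8, 9 of 11 genes had a promoter peak: Hoxa5, Hoxa6, Hoxb5 to Hoxb8, Hoxc5, Hoxc6 and Hoxd8. Hoxa7 had one in replicate 2 alone and Hoxc8 in neither.

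Long blocks of the mark lay within the clusters. On chromosome 11 a single peak of 48638 bp, from 96298895 to 96347532, covered the promoters of Hoxb3, Hoxb4, Hoxb5 and Hoxb6, and it was the widest promoter peak of the data. In the replicates' own lists the widest peak at this place had 40395 bp and 44151 bp. On chromosome 6, a peak of 12882 bp lay over Hoxa2, next to one of 11113 bp over Hoxa3 and 5730596B20Rik, and on chromosome 2 a peak of 9425 bp lay over Hoxd3. The widest promoter peaks of Hoxc6 and Hoxd8 had widths of 407 bp and 639 bp. The highest fold of a promoter peak per gene ranged from 11.3 to 24.3 in groups 1 to 4 and from 2.71 to 22.4 in groups 5 to 8. Against all other genes, groups 9 to 13 had a lower share of promoter peaks (6.25%, adjusted exact p = 0.000147), while groups 1 to 4 (83.3%, 0.110) and groups 5 to 8 (81.8%, 0.167) did not pass. Groups 5 to 8 passed with replicate 2 peaks alone (90.9%, adjusted exact p = 0.0484; range over 8 alternatives from 0.0484 to 0.380). With 1 member per 100 kb groups 9 to 13 did not pass (0%, adjusted exact p = 0.0602; range over 8 alternatives from 2.45e-05 to 0.0602). Genes of a cluster are neighbours that share peaks, and Hoxd3 and Hoxd4 have annotated 5' ends 2 bp apart. The contrast between Hox groups counted such genes as independent, and it was not run with 1 member per 100 kb. Covered lengths are taken around the outermost annotated start, which can lie at another gene of the cluster. The outermost start of Hoxa3 lies past Hoxa6, and that of Hoxc5 lies near Hoxc10. Hoxc5 had 0 bp within 5 kb and within 25 kb of that start, although it had a promoter peak of 3864 bp with a fold of 13.6.

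**Figure D3:**
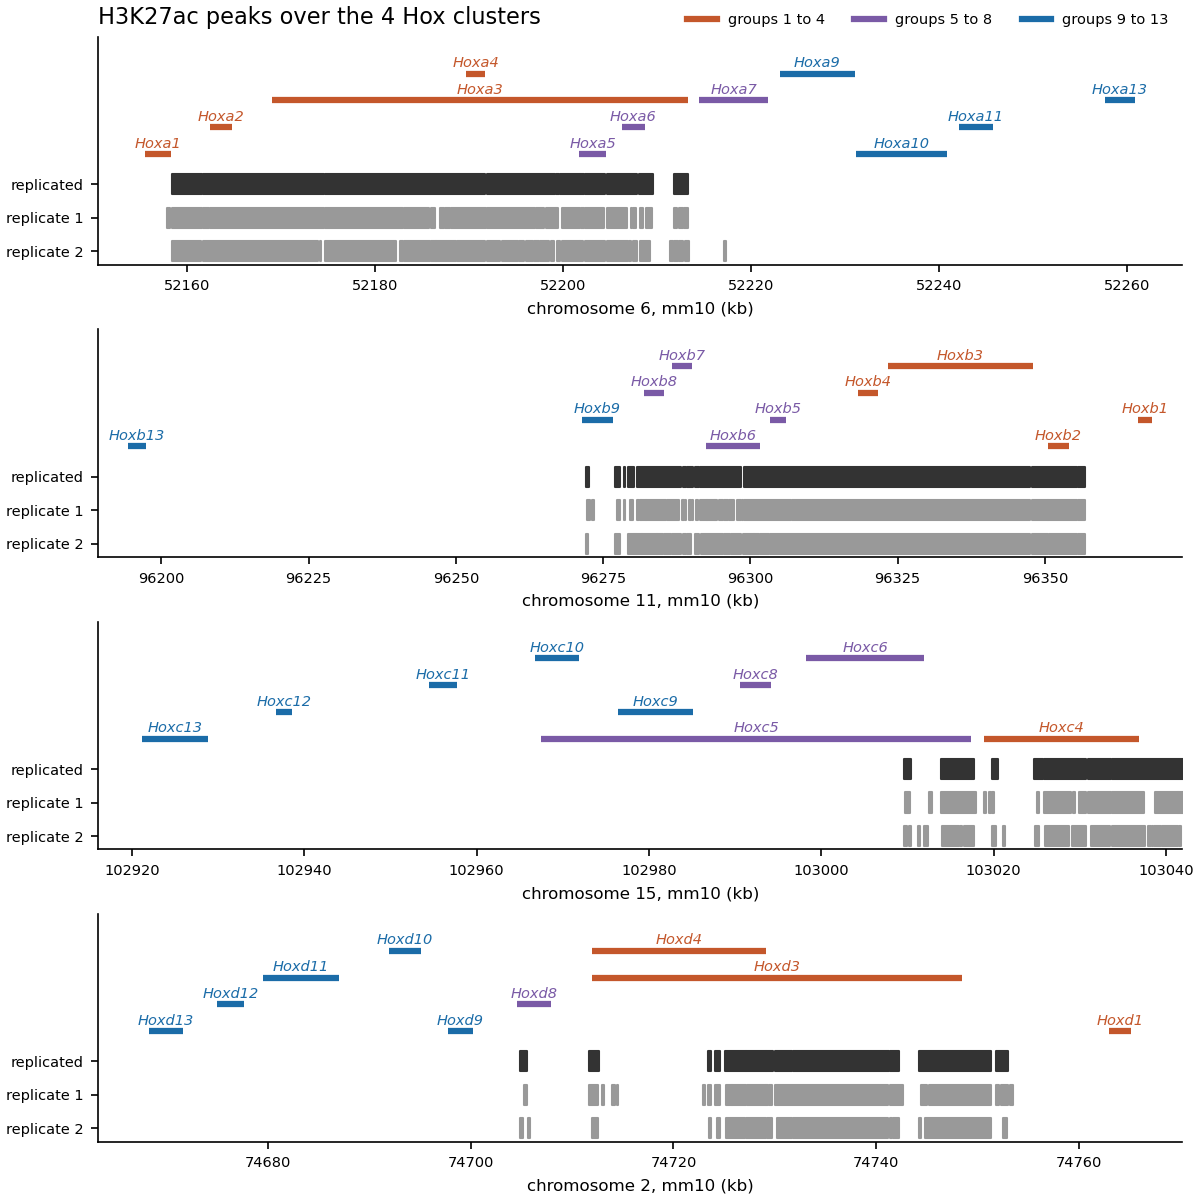
Peaks over the HoxA, HoxB, HoxC and HoxD clusters (horizontal axes, mm10 position in kb), with replicated peaks in black, the peaks of each replicate in grey, and genes of groups 1 to 4 in orange, 5 to 8 in purple and 9 to 13 in blue. Of the blue genes only Hoxb9 has a replicated promoter peak, and the orange genes Hoxb1 and Hoxd1 and the purple genes Hoxa7 and Hoxc8 have none.

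Regional and lineage genes were compared through gene lists. The granule and rhombic lip list names a lineage, so a contrast that includes it does not measure region alone. Whether members of the hindbrain and granule lists also act in the forebrain was not examined. The hindbrain list alone was not contrasted with the telencephalic list. Hindbrain and isthmus patterning factors, together with the granule and rhombic lip lineage, which also holds genes such as Ptch1, Reln and Cntn2 that encode no transcription factor, had a promoter peak at 38 of 44 genes (86.4%), and telencephalic and forebrain factors at 4 of 24 (16.7%; Fisher's exact p = 1.76e-08, two-sided). As single lists against all other genes, hindbrain factors had 15 of 19 (78.9%, adjusted exact p = 0.0961), and passed with replicate 1 peaks alone (84.2%, 0.0456; range over 8 alternatives from 0.0456 to 0.0973). Telencephalic factors were lower (adjusted exact p = 0.000342). The mean marked sequence within 25 kb was 10118 bp against 709 bp (permutation p = 1e-05, two-sided, the smallest possible). Among hindbrain factors, the transcription factor genes Meis2 with 28338 bp (26911 ± 2100 bp, n = 2), Meis1 with 18966 bp (18689 ± 955 bp, n = 2), Pax2 with 15751 bp (14439 ± 494 bp, n = 2) and Pbx3 with 10762 bp (10453 ± 67.9 bp, n = 2) had the most. Fgf8, the signal of the isthmus, Hnf1b and Phox2a had no promoter peak. Telencephalic factors without a promoter peak in either replicate included Arx, Dlx1 and Dlx2, each with 0 bp within 25 kb. The 4 telencephalic genes with a promoter peak were Bcl11b with 8183 bp (7776 ± 134 bp, n = 2), Lhx2 with 4125 bp, Hesx1 with 2022 bp and Satb2 with 1314 bp. Of these Hesx1 had its promoter peak in replicate 2 alone. Midbrain factors had a promoter peak at 7 of 15 genes (46.7%, adjusted exact p = 0.506), 10 in replicate 1 and 5 in replicate 2. En1, which acts at the border of midbrain and hindbrain, had 4156 bp (3621 ± 1332 bp, n = 2), Pou4f1 2984 bp and Nr4a2 2839 bp. Foxa2, Helt and Pitx2 had no promoter peak.

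**Figure D4:**
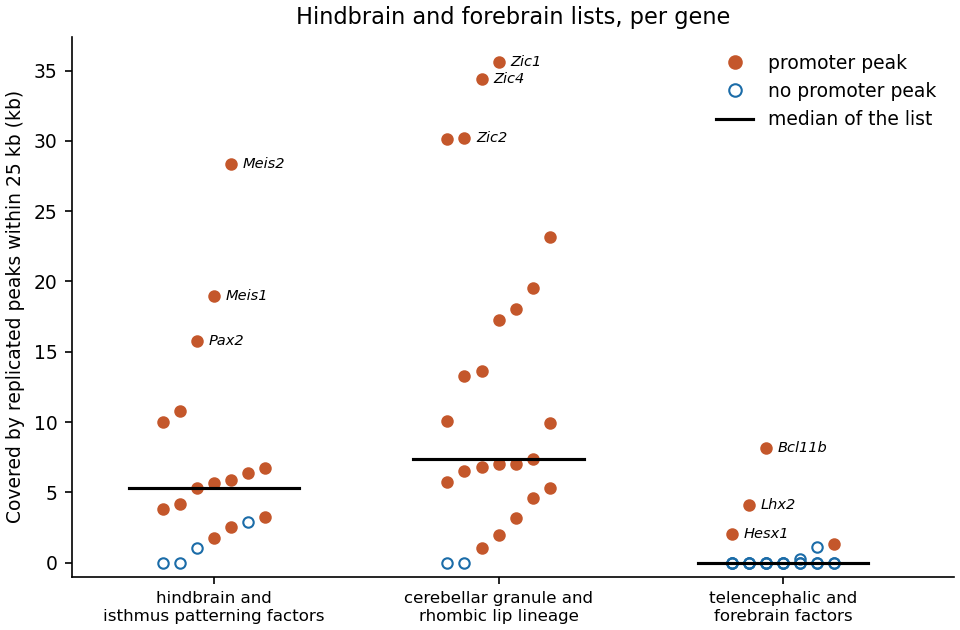
Marked sequence within 25 kb of each gene (vertical axis, kb under replicated peaks) for the hindbrain and isthmus, granule and rhombic lip, and telencephalic lists, with genes as points, filled where there is a replicated promoter peak. The medians, black lines, were 5332 bp for the hindbrain and isthmus list, 7356 bp for the granule and rhombic lip list and 0 bp for the telencephalic list.

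Markers of other cell types that the dissected tissue could hold were also examined. Endothelial genes had a promoter peak at 12 of 18 genes (66.7%, adjusted exact p = 0.520), 15 in replicate 1 and 11 in replicate 2. The share of 83.3% in replicate 1 passed (adjusted exact p = 0.0456; range over 8 alternatives from 0.0456 to 0.848). Sox18 had 6155 bp, Egfl7 5689 bp, Eng 4785 bp and Tal1 4023 bp. Choroid plexus genes had 8 of 15 (adjusted exact p = 0.832), with Foxj1, a factor of ciliated cells, at 8816 bp and Ttr, the transthyretin gene, at 1294 bp with a promoter peak in replicate 1 alone. Pericyte, fibroblast and meningeal genes had 6 of 16 (37.5%, adjusted exact p = 0.168), and were lower with -log10 q of at least 5 (18.8%, adjusted exact p = 0.00900) and with replicated peaks found in both replicates (25%, 0.0336; range over 8 alternatives from 0.00900 to 1), with Pdgfrb at 10896 bp and Foxc1 at 2774 bp. Microglia and macrophage genes had 0 of 16 (0%, 0% to 20.6%, adjusted exact p = 4.01e-05), 2 in replicate 1 and 1 in replicate 2. C1qa, C1qb and C1qc had no promoter peak, and Cd68, with 10454 bp in its surroundings, had one in replicate 1 alone. Erythroid genes had 0 of 13 (0% to 24.7%, adjusted exact p = 9.87e-05), 2 in replicate 1 and 0 in replicate 2.

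Lists of tissues outside the brain had few promoter peaks. Liver genes had a promoter peak at 1 of 17 (adjusted exact p = 9.87e-05), muscle genes at 3 of 17 (adjusted exact p = 0.00541) and epidermal genes at 2 of 14 (adjusted exact p = 0.00517), all lower than other genes. In replicates 1 and 2 the counts were 1 and 2 for liver, 3 and 3 for muscle, and 3 and 2 for epidermal genes. The median covered length of the muscle list was 1597 bp beside 1588 bp for all genes. Alb, Afp and Ahsg of the liver, Acta1, Actc1 and Ckm of muscle, and Dsc3, Dsg3 and Flg of the epidermis had no promoter peak in either replicate. Apoh, the liver gene with a peak, has an annotated start within 1 kb of one of Prkca, and Mylpf, one of the 3 muscle genes, within 1 kb of one of Tbc1d10b. Myh7, with a fold of 13.9, and the epidermal genes Lor (fold 22.4) and Krt10 (fold 27.9) had promoter peaks with no other coding start so near. With promoter windows of 2 kb the muscle list did not pass (29.4%, adjusted exact p = 0.0507; range over 8 alternatives from 0.00239 to 0.0507).

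The widest promoter peaks named further loci. After the HoxB peak came those of Meis2 (17580 bp), Tnrc18 (15313 bp), Meis1 (15204 bp), Thra, the thyroid hormone receptor alpha gene (13292 bp), Hoxa2, Zic1 (12529 bp), Ebf3 (12291 bp), Lhx1 (12205 bp) and Setd1b, a histone methyltransferase gene (12010 bp). Then came Nrn1, Zic4, Zmynd8, 5730596B20Rik, Nxph4, Gad1, Adgrg1, Gnai2, Mn1, Pou3f3, Zfhx3, 2700081O15Rik, Trim8, Hoxd3 and, with 9365 bp, Zfp532. Gad1 encodes the enzyme that makes the transmitter GABA. Among the 25 genes of the widest peaks, 16 were also found with the list of replicate 1 alone and 14 with that of replicate 2 alone.

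Joined over gaps of up to 10 kb, the largest marked stretch lay at Msi2, an RNA-binding protein gene of neural stem cells. It spanned 344 kb on chromosome 11, from 88375511 to 88719814, with 122 peaks and 164 kb under them. Next came Ebf3 with 84.2 kb on chromosome 7, a stretch on chromosome 2 that holds 1700001O22Rik and Ntmt1 with 78.5 kb, and the HoxB cluster with 76.7 kb from Hoxb2 to Hoxb9. The remaining 6 held Gse1, Gm20388 and Gins2 (68.0 kb), Rhcg (65.3 kb), Ncor2, a corepressor gene (53.6 kb), Myo18a, Pipox and Sez6 (52.8 kb), the HoxA cluster from Hoxa2 to Hoxa6 with Gm28308 and 5730596B20Rik (51.1 kb), and Src, Blcap and Nnat (50.4 kb). The order depended on the gap, since with a gap of 5 kb the HoxB stretch was the largest with 76.7 kb. With a gap of 20 kb the largest was a stretch from Srsf1 to Msi2 with 246 kb under peaks.

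Of the 10 peaks of highest fold over 5 kb from any start, the top one had a replicated fold of 39.98 and lay between genes on chromosome 8, from 69716202 to 69717719, 6.24 kb from the 5' end of Zfp869. The others lay nearest to Chd2 (fold 39.3), Pum2 (39.1), Cstad (37.6), Snx10 (37.1), Ppara (35.6), Anp32e (34.6), Tex44 (33.8), Tuba1a (32.3) and Myo3a (31.8). The peaks near Cstad, at 64.1 kb, and Ppara, at 64.7 kb, lay in introns of noncoding genes and the other 8 lay between genes. Each of the 10 had a peak in both replicates. The nearest gene is a position and not a target.

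Across chromosomes, chromosome 11 had the most replicated peaks for its length, 36.3 per Mb, but per protein-coding gene its 2.70 peaks lay near the autosome median of 2.73. The autosomes had a median of 22.0 per Mb and a lowest value of 16.7 per Mb, on chromosome 3. The X chromosome had 938 peaks, 5.48 per Mb, and the Y chromosome had 5 peaks. A promoter peak was present at 42.4% of the protein-coding genes of the X, below the lowest autosome (46.3%, chromosome 7). Per protein-coding gene the X had 0.989 peaks and the autosomes between 1.75 and 3.88.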

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

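Peaks on sequences not placed on a chromosome drew attention because no comparison with shifted lists or genes used them; no test was run on them beyond the counts, which were made after the data were seen. Replicate 1 had 13 such peaks and replicate 2 had 12. These counts only show that such peaks were called. The replicated list held 10 of them, on 5 sequences, with a highest fold of 40.5. No explanation of these peaks was tested, and they entered only the description of the whole lists and the comparison of the replicated list with the other lists.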

How the results depend on the processing

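The replicated peaks that overlap a peak of both replicates, and the other overlap rules for the comparison by decile, were chosen after the data were seen; the other alternatives were planned. The share of peaks common to the replicates stayed above shifted lists under every overlap rule and threshold tried, from 36.7% to 80.2% of the peaks of replicate 1 and from 41.6% to 82.5% of those of replicate 2. The share of peaks in promoters stayed higher and the share between genes lower than in shifted lists under all alternatives, with each replicate left out in turn as well. Both contrasts, Hox groups 1 to 4 against 9 to 13 and the hindbrain and granule lists against the telencephalic list, also kept their direction. The alternative with 1 member per 100 kb was run for the hindbrain and granule contrast only. How far shared peaks of neighbouring genes carry the Hox contrast was therefore not tested.

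With -log10 q of at least 5, the counts of peaks fell to 32929 in replicate 1, 31507 in replicate 2 and 47248 in the pooled list, as a stricter threshold must. At that threshold the share of peaks in introns turned from higher than shifted lists to lower (38.1%, permutation p = 0.099, not past the threshold), and that in exons no longer passed (3.42%). With replicated peaks found in both replicates, introns (39.7%) and exons (3.43%) were higher without passing. The cause was not tested. By decile of fold, the overlap rule moved the shares as its strictness requires. In decile 1, asking for 50% of both peaks gave 92.9% for replicate 1 and 92.3% for replicate 2. In decile 10, 1 bp gave 35.9% and 51.9%, and 50% of both peaks gave 15.1% and 21.5%.

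Of the 15 gene lists called by promoter peaks, at least 12 were kept on the same side in each alternative, and all 9 lists called by their surroundings were kept in each. The number of higher promoter lists, 6 with replicated peaks, was 8 to 11 without replicate 1 or 2. The number of lists with lower surroundings, 0 with replicated peaks, where 6 lists had the lowest possible median of 0 bp, was 2 with 50 kb windows (telencephalic and epidermal), 2 with random lists matched on gene density and 2 with the pooled list (in both, telencephalic and Hox groups 9 to 13), and 1 to 1 without replicate 1 or 2 (telencephalic). The median of Hox groups 9 to 13 changed from below random lists to above them with 50 kb windows (6099 bp). The cause of these changes was not tested.

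The widest promoter peak lay at Hoxb3 in every setting and had 40.4 to 44.2 kb without replicate 1 or 2. Of the 25 genes with the widest peaks, 14 to 16 were shared without replicate 1 or 2. The largest merged group had 76.7 kb with a gap of 5 kb, at HoxB, and 246 kb with a gap of 20 kb, which joins more peaks by construction, and 141 to 162 kb without replicate 1 or 2. The peaks per Mb on the X, as a percent of the median autosome, were 28.8 with -log10 q of at least 5, 26.6 with peaks found in both replicates, and 20.0 to 20.96 without replicate 1 or 2, low in each. Around the 61 genes whose covered lengths are compared here, replicate 2 alone covered a median of 89.1% of the replicated length (from 53.1% at Nr4a2 to 107% at Mcm2) and replicate 1 alone 95.3% (from 47.6% at Ret to 167% at Tbx3). Read depth is unknown, so what it limits could not be measured.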

Other observations

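The tests in this part were chosen after the results they concern were seen, except that the test of promoter folds on the X was written before its value was known. The gene families of the last paragraph were also chosen after the peaks were seen.

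The replicated list held 9694 peaks that overlapped a peak of only one replicate or of neither by at least 50% of either peak. A stricter overlap rule here than the authors used would predict almost none at 1 bp, but 16.8% of the list still lacked a replicate at 1 bp, which argues against it as the whole cause. Weak peaks missed in one replicate may be part of the cause. The 9694 peaks had a median -log10 q of 4.51, below the lower quartile of 6.55 of the peaks found in both. That difference cannot decide it, because peaks absent from a replicate's list would tend to be weak whatever let them into the replicated list. The list left out 0 pooled peaks that overlapped both replicates by at least 50% of either peak, and 542 that did so by 1 bp. Overlap with both replicates' own lists cannot have admitted the 9422 peaks that lacked a replicate at 1 bp. These 9422 entered the list by another way. Of them, 457 overlapped no peak of either replicate by 1 bp, so overlap with a single replicate cannot have admitted those. What the other way was could not be tested. The rule of the list is not given in the sources used here, and weak peaks and another way into the list do not exclude each other. No biological explanation was tested, since the design has a single group.

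The X chromosome had 5.48 replicated peaks per Mb, against 16.7 to 36.3 on the autosomes. Silent genes alone would leave the number of peaks per gene with a promoter peak in the range of the autosomes, but the X had 2.33 and the lowest autosome 3.45, which argues against them as the whole cause. The value of 2.33 follows from counts that had been seen. Non-promoter peaks made most of the gap, with 0.965 per such gene against 2.10 to 4.85. One active X copy per cell was set to predict a lower promoter fold on the X, and the fold was 8.33, within the 7.11 to 8.48 of the autosomes. This was not read as evidence against it, because that bound assumed that peaks on the X and the autosomes are called at similar folds. The other peaks of the X had a median fold of 3.71, above every autosome (3.34 to 3.43), so that weak peaks there may be missing from the list. Lower read coverage of the X in pools of both sexes would raise the fold needed for a given significance. Among peaks with -log10 q from 5 to 7 the median fold was 3.28 on the X and 3.16 to 3.19 on the autosomes, which fits it with a small difference. This test was devised after the 3.71 was seen, and how much of the deficit coverage could make was not tested. Copy number, a lower mark on the X and fewer enhancers stay open.

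Hox groups 5 to 8 carried promoter peaks at 9 of 11 genes, although groups 1 to 4 are those used along most of the hindbrain. Spread of one broad peak from groups 1 to 4 would place all of them under peaks shared with those groups. Instead, 8 of the 9 had a promoter peak that reached no promoter of groups 1 to 4 (all but Hoxb5). That argues only against a single called peak over all of them, because short gaps can split a broad block into several peaks. At HoxB, a peak of replicate 1 ended at 96306941 and the next began at 96307081, inside the 48638 bp replicated peak. Joined over gaps of up to 5 kb, the peaks from Hoxb2 to Hoxb9 made a single stretch with 76.7 kb under them. The test cannot tell such a block from separate peaks. Spinal cord from the trunk in the tissue might bring marked genes of groups 9 and 10, and of these 1 of 7 (Hoxb9) had a promoter peak. That value cannot be told apart from spinal cord of the neck, which uses groups 5 to 8 and would leave groups 9 and 10 unmarked, or from the hindmost hindbrain itself. The peak lists hold no measure of where the tissue was cut.

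Outside the fixed gene lists, genes were grouped by the stem of their symbol, which gave 152 families of at least 15 members. Of these 64 had a higher and 45 a lower share of promoter peaks than other genes (Fisher's exact test, Benjamini-Hochberg adjusted). All members had a promoter peak among the mitochondrial ribosomal protein genes Mrpl (49 of 49) and Mrps (29 of 29), the Mediator genes Med (30 of 30), the RNA polymerase genes Polr (28 of 28) and the histone demethylase genes Kdm (18 of 18), and 325 of 394 Zfp genes had one. The olfactory receptor genes Olfr (1 of 1135), the vomeronasal receptor genes Vmn1r (1 of 209) and Vmn2r (0 of 122), the beta-defensin genes Defb (0 of 42), the Rhox genes (0 of 34) and the clustered protocadherin genes Pcdhb (0 of 22) were almost without replicated promoter peaks. In replicate 1, Olfr and Pcdhb had 2 each. Members of such families lie side by side and are alike in sequence, so they are not independent, and the placement of reads that match several copies was not examined.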
